A study of Escherichia coli with 5 samples.

How the data were processed

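Each of the 5 samples is a 2-colour array on which cDNA of a 37°C culture and a 23°C culture was hybridised together. Per the labels' protocols, cDNA came from 2 µg of total RNA, the dyes were Cy3 and Cy5, and the slides carried full-length PCR products of 4290 open reading frames of strain MG1655. Per the labels, arrays 4 and 5 are dye-flipped technical replicates of arrays 2 and 3. The scanner, the background correction, the normalization and the spot filter are not given in the sources used here.

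The deposited table of spots holds a linear ratio per spot and array, normalized by the authors in a way its header does not state. Its 9792 spots include 866 control spots under 107 names, which were left out. Of the ratios, 14035 are exactly 1, against 33 at 0.999 and 30 at 1.001, and 959 of 960 values of blank spots are exactly 1, so an exact 1 was read as a spot with no value. The second deposited table, the series matrix, holds log2 ratios in 3925 rows without gene names. By value, within 0.0021 log2 units, 3850 of its rows matched 1 gene each: 3507 equalled the mean log2 ratio of the gene's spots and 343 a single spot. In the former, 1293 cells of genes with no measured spot held the median of the row's measured arrays, which lowers the spread between arrays. Its column medians were -0.06, -0.03, -0.05, -0.01 and -0.01 after the turn of sign, its direction is that of the spot table, and its centring method stays unknown. The plan set before the data were examined made the matrix the main table unless its gene names could not be settled. It carries none, and its rows could be named only by their values, through the spot table. The spot table was therefore made the main one and the matrix an alternative, which is a judgement, since 3850 of 3925 rows did match.

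Ratios were turned to 37°C over 23°C, log2 transformed and averaged over the spots of a gene, usually 2. No further normalization was applied. Of the 4290 feature names, 4162 matched the RefSeq gene table of assembly ASM584v2, 2685 by symbol, 525 by locus tag and 952 by synonym, and 128 kept the name in the file; 104 names share a locus with another. That table served for names and for which genes are neighbours. List members were found by symbol or, for names since changed, by synonym. The pap fimbriae list was matched by name alone, because the table's pap synonyms are old names of ATP synthase genes, and it had no feature.

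The replicate was the culture pair (n = 3): array 1, the mean of arrays 2 and 4, and the mean of arrays 3 and 5. An SD with n = 3 is taken over these 3 values. It leaves out the difference between the 2 arrays of a pair, which was large for some genes. Genes with a value in all 3 pairs were tested with limma 3.58.1 in R 4.3.3, an intercept against 0 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment at 0.05. The fit had 2 residual and 4.54 prior degrees of freedom. With 3 pairs, a sign-flip permutation test of 1 gene cannot give an exact p below 0.25, so all calls rest on limma's model. Gene lists were fixed before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, with camera at a correlation estimated from the same 3 values, and with fry. Correlations estimated from so few values are imprecise. With an estimated correlation, camera also judges a list on the 2 residual degrees of freedom, which makes a call hard to reach. The general stress list had an estimated correlation of 0.00024, below the preset value. Its camera adjusted p still went from 9.29e-24 to 0.207. A call lost in this form of the test does not by itself show correlation between genes.

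The named genes followed a rule fixed before the data were examined: the 10 largest mean ratios each way among called genes with 1 sign on every array that measured them; hisJ, cysP, srlE, garP, fes, cirA, papB and papA as far as measured; up to 4 called members per list, or the 2 largest as not passing; and lacZ, lacY and lacA. rpoS in the results, and the genes the closing section adds, lie outside the rule and were chosen after their values were seen. The alternatives tried were all 5 arrays with the culture pair as a random block, with and without a dye term; weights by number of arrays; centring, scaling and quantile normalization; the series matrix; other coverage filters; robust or no moderation; leaving out each culture pair and each of arrays 2 to 5; and arrays of 1 dye orientation with array 1. Added after seeing the data were exact 1s read as unchanged and values from both spots only.

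The fit was tested on simulated data with 200 genes changed, in 20 draws. Errors were normal, independent between genes and equal in size across culture pairs, with the moderated spread of the 3539 genes. It recovered 66.6% of 2-fold and 99.8% of 4-fold changes, 5.19% of its calls were false and 0 had the wrong sign. Such draws meet the model's own assumptions, so these shares do not give the rate of false calls in the real data.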

Results

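Transcript levels of Escherichia coli K-12 MC4100, a laboratory strain, were compared between cultures grown at 37°C and at 23°C in M9 medium with glycerol as carbon source. The question, per the series' design text, was which genes are expressed at different levels in cells adapted to each temperature over long growth, 37°C being the temperature of the human body. Both cultures of a pair came from 1 colony and were harvested in exponential phase, at an OD600 of 0.2 to 0.6, after 9 to 11 generations. The RNA of both temperatures was hybridised together on each of 5 arrays spotted with PCR products of 4290 open reading frames. Arrays 2 and 4 held culture pair 2 in opposite dye orientations, arrays 3 and 5 held culture pair 3 in the same way, and array 1 held culture pair 1 in 1 orientation, so that n = 3 culture pairs. The arrays gave a value for 80.5%, 54.8%, 90.8%, 83.8% and 70.0% of their open reading frame spots, in the order 1 to 5. Signal intensities were not analysed here. The number of culture pairs and arrays limits the precision.

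All ratios are given as 37°C over 23°C, and this direction is likely, not stated: the sources used here do not name the numerator of the deposited ratio. Its basis is the title of the paper cited in the labels, which places iron, carbohydrate and amino acid utilization genes higher at 37°C, and these genes lay below 1 in the deposited ratio. Those groups are therefore no independent evidence of the direction, and every sign below would turn if the direction were the other one. The counts of higher and lower genes and lists would then change places; sizes, total counts and the grouping of genes into opposite directions would stay.

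Genes of acid resistance, curli fibres and the general stress response were far lower at 37°C than at 23°C, and the lac operon and some genes of iron uptake and sulfate assimilation were higher. For the lower groups a difference in growth phase between the cultures cannot be told apart from temperature. Of the tested members 14 of 17, 16 of 26 and 29 of 34 were called lower in the first 3 lists; 3 of 3 lac genes, 12 of 35 and 10 of 24 were called higher. Camera called these 6 lists with a preset correlation and none with an estimated one, where their adjusted p-values were 0.207, 0.380, 0.207, 0.398, 0.380 and 0.380 in that order. The latter form of the test also rests on 2 residual degrees of freedom, so its lack of calls does not single out correlation within lists. The largest fall was in csgA, the major curli subunit, at a log2 ratio of -4.49 ± 0.13 (SD, n = 3), a 22.4-fold difference (limma adjusted p = 0.000494). The largest rise was in lacZ, beta-galactosidase, at 4.01 ± 1.07 (SD, n = 3), 16.1-fold (adjusted p = 0.00303). The textbook genotype of MC4100 lacks the lac genes, so this rise cannot be read as that of a native lac operon, and its source was not settled. Of 3539 genes with a value in all 3 culture pairs, 313 changed between the temperatures at an adjusted p under 0.05, of which 89 were higher and 224 lower at 37°C. At least 2-fold changes made up 281 of them, 75 higher and 206 lower. All 313 had the same sign in the 3 culture pairs, and 300 had it on every array that measured them. Over all tested genes 46.4% had 1 sign in the 3 pairs, against 25% by chance.

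The count depends on moderated variances and on culture pair 1: limma without moderation called 0 genes, with 589 at an unadjusted p under 0.05, and without culture pair 1 the fit called 8 genes, with 470 at an unadjusted p under 0.05, among them lacZ at a ratio of 3.42 and an adjusted p of 0.0518, whereas without culture pair 3 it called 501. Of the 61 named genes that passed, 8 passed without culture pair 1, 47 without culture pair 2 and 60 without culture pair 3. None of them turned direction under any of the 22 alternatives. Because every called gene had the same sign in all culture pairs, leaving out or weighting culture pairs could not turn one, so this is little evidence of stability. Reading the spots deposited at exactly 1 as unchanged, a choice made after seeing the data, gave 135 genes, with 28 of the 61.

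**Figure D1:**
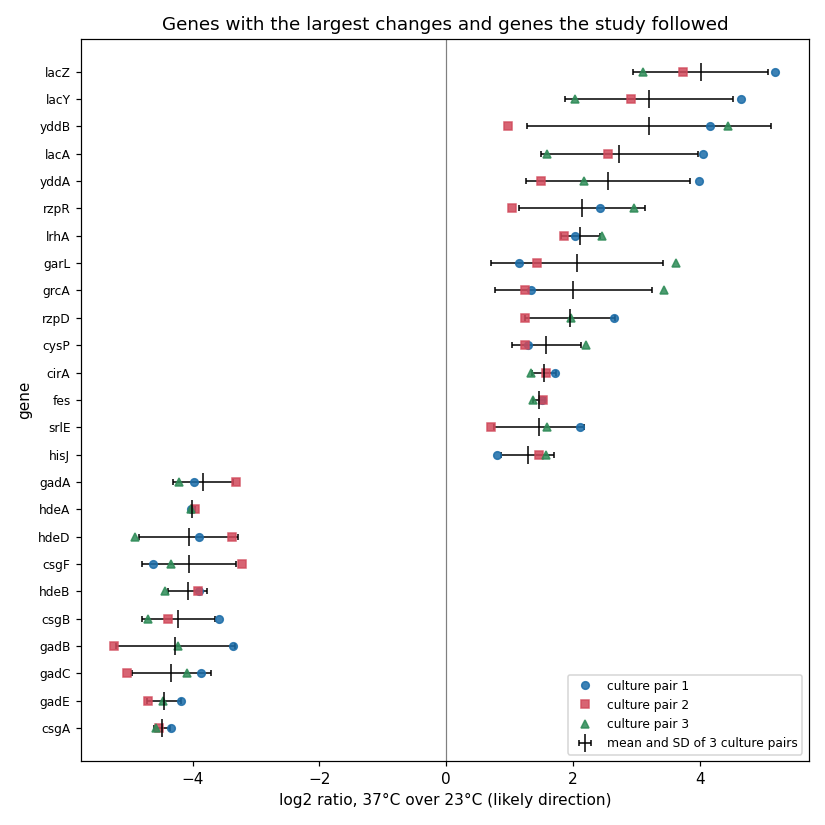
Log2 ratio of 37°C over 23°C (x axis, likely direction) for the 10 genes with the largest called changes each way and for genes the study followed (y axis). Coloured symbols are the 3 culture pairs, black bars the mean and SD. Every gene shown has its 3 symbols on 1 side of 0, from csgA at a mean of -4.49 to lacZ at 4.01.

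Acid resistance genes formed the group with the lowest median ratio. Of 17 members tested, 14 fell at 37°C and none rose, with a median log2 ratio of -3.73, a 13.3-fold difference. Adjusted over the list alone, 15 fell. gadE, the central activator of the glutamate-dependent acid resistance system, fell by 4.45 (SD 0.27, adjusted p = 0.000494). gadC, its glutamate antiporter, had a ratio of -4.34 ± 0.62 (SD, n = 3), and the glutamate decarboxylase genes gadB and gadA had -4.27 ± 0.94 and -3.84 ± 0.47. gadA and gadB are near-identical copies whose full-length PCR products can cross-hybridise, so their values are uncertain as separate measurements. The periplasmic chaperone genes hdeA and hdeB had ratios of -4.01 ± 0.04 and -4.08 ± 0.31, and hdeD, a membrane protein gene beside them, -4.07 ± 0.78. These SDs hide differences between arrays 2 and 4 of culture pair 2, with hdeA at -3.13 and -4.80 and gadA at -1.50 and -5.14. Camera with a preset correlation placed the list below other genes (adjusted p = 6.03e-17), but with an estimated correlation the adjusted p = 0.207.

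Curli and biofilm genes fell in 16 of 26 tested members, with 10 not passing the test and a median of -1.73. Adjusted over the list alone, 17 fell. Beside csgA, the nucleator gene csgB had a ratio of -4.23 ± 0.58 (SD, n = 3), csgF, of curli assembly, -4.07 ± 0.74, and csgC, also of the curli system, -3.84 ± 1.29. The camera adjusted p = 4.73e-11 with the preset correlation, and adjusted p = 0.380 with an estimated correlation.

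Genes of the general stress response, which depends on the sigma factor RpoS, fell in 29 of 34 tested members, and 1 member had a ratio above 0. The median was -1.82, or 3.54-fold, and the medians of the 3 culture pairs had an SD of 0.11. Adjusted over the list alone, 31 fell. dps, which encodes a DNA-binding protein of starved cells, had a ratio of -3.48 ± 0.38 (SD, n = 3), osmY, a periplasmic protein gene induced by osmotic stress, -3.18 ± 0.15, yeaG, a protein kinase gene, -3.09 ± 0.08, and its neighbour yeaH -3.00 ± 0.69. The camera adjusted p = 9.29e-24, and adjusted p = 0.207 with an estimated correlation. rpoS itself had a ratio of -1.21 ± 0.52 (SD, n = 3; adjusted p = 0.0396).

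Siderophore and iron uptake genes, a group named in the title the direction was taken from, were higher at 37°C. Of 35 tested members 12 rose and 0 fell at an adjusted p under 0.05, 33 had a ratio above 0, and the median was 0.83, or 1.78-fold. Adjusted over the list alone, 22 rose and 1 fell. fecR, of ferric citrate regulation, had a ratio of 1.81 ± 0.54 (SD, n = 3), and fecA, the ferric citrate receptor gene, 1.42 ± 0.51. cirA, a catecholate siderophore receptor gene, had 1.54 ± 0.19, and fes, which encodes the enterobactin esterase, 1.47 ± 0.09. Camera gave an adjusted p = 3.40e-13, and adjusted p = 0.380 with an estimated correlation. The list of iron-rich proteins repressed under low iron had 6 of 9 members above 0 and a median of 0.44 (0.17, 1.03 and 0.12 in the 3 culture pairs) and was not called. Its 1 member that passed went the other way: acnA, the stationary-phase aconitase, fell by 1.12 (SD 0.21). Most of this list, namely acnA, acnB, fumA and the sdh genes, is also in the TCA cycle list below, so those lists are not separate readouts. None of the 6 Suf iron-sulfur assembly genes passed, with sufA at 0.46 ± 0.34 and sufC at 0.19 ± 0.15.

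Sulfate uptake and cysteine synthesis genes rose in 10 of 24 tested members, with a median of 0.89, or 1.85-fold, and 13 passed adjusted over the list alone. The sulfate and thiosulfate binding protein gene cysP had a ratio of 1.58 ± 0.54 (SD, n = 3), the permease gene cysU 1.41 ± 0.58, the sulfite reductase gene cysJ 1.40 ± 0.20 and the adenylylsulfate kinase gene cysC 1.39 ± 0.57. Camera gave an adjusted p = 1.52e-07, and adjusted p = 0.380 with an estimated correlation.

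Amino acid genes moved by less. In the uptake list 3 of 47 tested members rose and 44 did not pass, with a median of 0.29, and 5 rose adjusted over the list alone. The 3 were hisJ, the histidine binding protein gene, at 1.28 ± 0.42 (SD, n = 3), hisQ of the same transporter at 1.11 ± 0.38, and the lysine permease gene lysP at 1.19 ± 0.34. Within culture pair 2, lysP was at 1.82 on array 2 and -0.12 on array 4. For the uptake list camera gave an adjusted p = 0.00240, and adjusted p = 0.349 with an estimated correlation. With arrays 1, 4 and 5 alone the camera adjusted p was 0.0546. In the synthesis list 5 of 76 members rose, among them lysC at 1.49 ± 0.87, asnA at 1.28 ± 0.53 and argD at 1.25 ± 0.24, and 2 fell, with metF of methionine synthesis at -1.28 ± 0.49. Its median was 0.39, 13 rose and 3 fell adjusted over the list alone, and camera gave an adjusted p = 4.38e-07, and adjusted p = 0.207 with an estimated correlation. In the breakdown list 1 of 24 members passed, gcvP of the glycine cleavage system at 0.95 ± 0.30, against a list median of -0.31 (camera adjusted p = 0.354).

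Carbohydrate genes went both ways. Of 99 tested members 7 rose and 2 fell, with a median of 0.19, and adjusted over the list alone 17 rose and 2 fell. Without array 3 the median was 0.13 (camera adjusted p = 0.0387). garL, of galactarate breakdown, rose at 2.07 ± 1.35 (SD, n = 3) and was at 1.29 without culture pair 3, mglA, of galactose uptake, at 1.77 ± 0.27, and srlE, of the sorbitol transporter, at 1.46 ± 0.71, whereas treA, the periplasmic trehalase gene, fell by 2.42 (SD 0.62). treA is also a member of the general stress list, so its fall is not a separate reading of carbohydrate use. srlE lost its call when each array was centred and scaled. Camera gave an adjusted p = 0.00139, and adjusted p = 0.301 with an estimated correlation. With arrays 1, 4 and 5 alone the median was 0.12 and the adjusted p 0.0828. In the narrower list of hexitol and sugar acid use 4 of 26 members rose, with srlB at 1.26 ± 0.66 and srlD at 0.99 ± 0.35 beside garL and srlE, and adjusted over the list alone 8 rose and 1 fell. Its median was 0.28 and its camera adjusted p = 0.0102, with adjusted p = 0.440 with an estimated correlation. Without array 3 the median turned to -0.0079 and the call was lost (camera adjusted p = 0.0781), and the median was 0.14 without array 4 and 0.43 without culture pair 1. garP, a galactarate transporter gene the study followed, had no value in culture pair 1 and was not tested. Its ratios were 0.80 and 1.44 on the arrays of culture pair 2 and 4.59 and 3.63 on those of culture pair 3. The 8 genes named beforehand as followed by the study included papA and papB, and no array feature carried a pap name.

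No single gene passed in the lists of glycerol use, with glpA at 0.87 ± 0.32 (SD, n = 3) and glpQ at 0.79 ± 0.47, or of maltose use, with malM at 1.14 ± 0.80 and lamB at 1.10 ± 0.58. As lists they had medians of 0.42 and 0.45 and camera adjusted p-values of 0.00812 and 0.00248, and adjusted p = 0.380 for both with an estimated correlation. The maltose median was 0.29 without array 2. The glycerol list lost its call without culture pair 2 (median 0.41, camera adjusted p = 0.0664) and without array 3 (median 0.18, adjusted p = 0.0716). Adjusted over the list alone, 3 of 11 maltose genes rose and 0 of 12 glycerol genes. The TCA cycle list had a median of 0.54 and a camera adjusted p = 0.00253 (adjusted p = 0.595 with an estimated correlation), although acnA, which fell, was its 1 called member. Without culture pair 2 the median was 0.28 and the list was not called (camera adjusted p = 0.0796). The ATP synthase list had a median of 0.41 and a camera adjusted p = 0.010 (adjusted p = 0.607 with an estimated correlation) with 0 of 9 members called, atpF at 0.64 ± 0.24 and atpD at 0.63 ± 0.34. Without culture pair 1 its median was 0.20 and it was not called (camera adjusted p = 0.152), and without culture pair 3 the median was 0.66. Ribosomal protein genes had a median of 0.11 and 0 of 52 members called, with rpsG at 0.71 ± 0.41 and rpmI at -0.61 ± 0.47. Their camera adjusted p was 0.0436, with adjusted p = 0.607 with an estimated correlation, and with arrays 1, 4 and 5 alone the median turned to -0.09. This call was also lost without culture pair 1 (median 0.06, camera adjusted p = 0.325), culture pair 3 (0.11, adjusted p = 0.136), array 2 (0.03, adjusted p = 0.322) or array 3 (0.02, adjusted p = 0.415). The median was 0.17 without culture pair 2 and 0.21 without array 4 or array 5.

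Heat shock genes lay lower at 37°C as a list, with a median of -0.48 and 19 of 20 members below 0 (camera adjusted p = 0.00248, and adjusted p = 0.595 with an estimated correlation). Without culture pair 2 the list was not called (median -0.34, camera adjusted p = 0.0796). The 1 member that passed was groS, the small chaperonin gene, at -1.29 ± 0.18 (SD, n = 3). Of 15 cold shock genes, 1 fell at 37°C: cspI, a cold-inducible member of the CspA family, at -1.98 ± 0.42. The list's median was -0.11 (camera adjusted p = 0.242), and without culture pair 3 it was -0.56 and the list was called (adjusted p = 0.0247). Members of the CspA family resemble each other in sequence, so spotted PCR products can read more than 1 of them.

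Among outer membrane porin and protein genes 2 of 9 rose and 2 fell. ompT, a protease gene, had a ratio of 1.72 ± 0.23 (SD, n = 3) and ompW 1.70 ± 0.55, whereas the porin gene ompC had -2.64 ± 0.68 and ompX -1.48 ± 0.08. ompX was also the 1 called member of 14 in the envelope stress list. Of 30 genes of anaerobic respiration and hydrogenases 3 rose and 2 fell, with the nitrite reductase gene nirB at 1.79 ± 0.32, hybO of hydrogenase 2 at 1.02 ± 0.39, and hyaA and hyaB of hydrogenase 1 at -1.04 ± 0.22 and -1.18 ± 0.47. hyaB was at -0.74 without array 2 and not called. The list's median was -0.10 whereas its mean was 0.01 and camera's direction was up, short of the threshold (adjusted p = 0.589). The capsule activator gene rcsA fell at -2.11 ± 0.91 as 1 of 12 colanic acid genes. cfa, the cyclopropane fatty acid synthase gene, at -2.16 ± 0.50, was the 1 called gene of 21 in the membrane lipid list, whose median of -0.0049 and camera direction, up, differed in sign (adjusted p = 0.354). Of 11 nucleoid protein genes dps and cnu fell, cnu at -1.10 ± 0.39, and of 23 nucleotide synthesis genes carB rose at 1.40 ± 0.50. The camera adjusted p-values of the porin, envelope stress, colanic acid, nucleoid and nucleotide lists were 0.276, 0.501, 0.170, 0.276 and 0.409. The colanic acid list was called without culture pair 2 (median -0.38, camera adjusted p = 0.0279), and without culture pair 3 its median turned to 0.06.

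No member passed in the lists of flagella and chemotaxis (43 tested), type 1 fimbriae (8), glycolysis (12) and the aerobic respiratory chain (19). The members with the largest ratios were flgD at -1.05 ± 0.65 (SD, n = 3) and flgE at -0.85 ± 1.29, fimD at 0.49 ± 0.70 and fimE at 0.38 ± 0.53, pfkB at -0.72 ± 0.04 and gpmM at 0.65 ± 0.42, and nuoK at 0.50 ± 0.43 and nuoA at 0.33 ± 0.30. Within culture pair 3, flgD was at 0.32 on array 3 and -3.91 on array 5. The flagella list was called without array 4 (median -0.43, camera adjusted p = 0.0264) and the respiratory chain list without culture pair 3 (median 0.23, adjusted p = 0.0377). The camera adjusted p-values of the 4 lists over all culture pairs were 0.701, 0.242, 0.990 and 0.129, and those of the iron-rich protein and Suf lists 0.259 and 0.354.

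**Figure D2:**
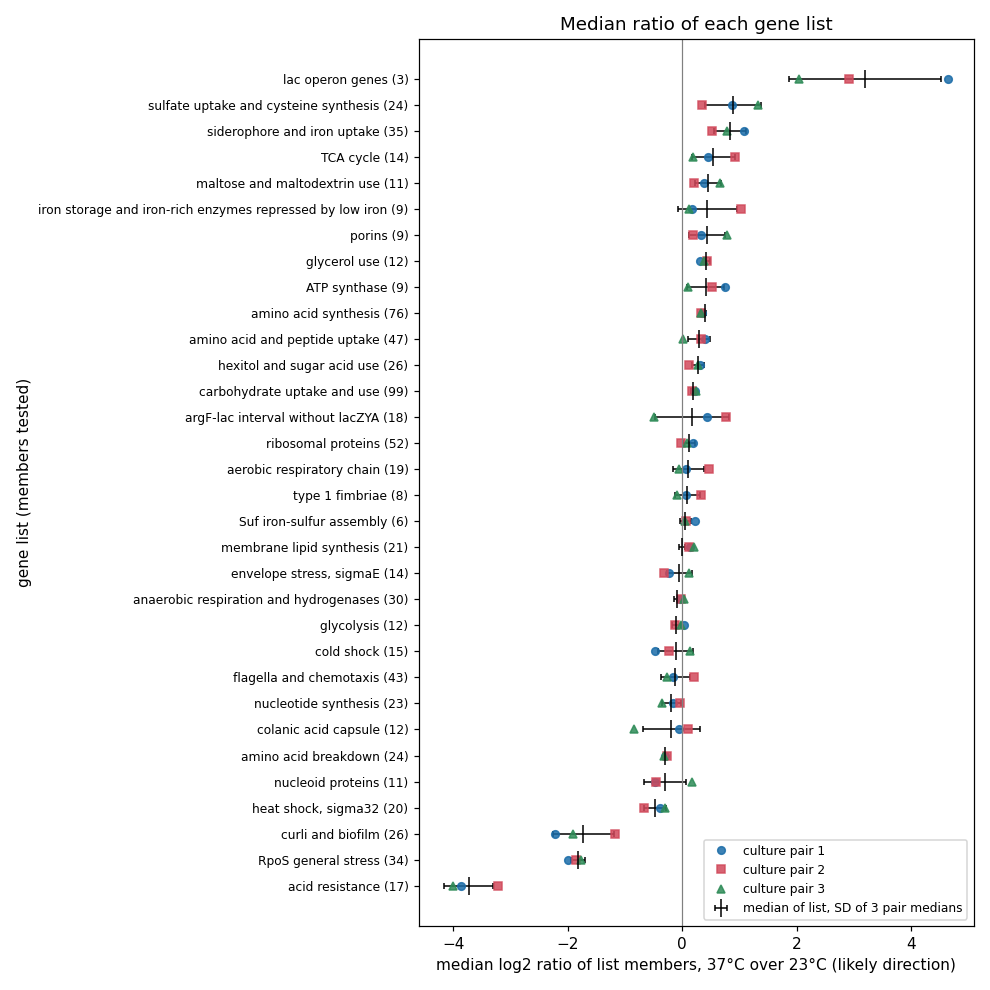
Median log2 ratio of 37°C over 23°C (x axis, likely direction) of the 32 gene lists (y axis, members tested in parentheses). Coloured symbols are the medians in the 3 culture pairs, black marks the median of the member means with the SD of the pair medians. The acid resistance list lies lowest at -3.73 and the lac genes highest at 3.20.

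The lac genes rose together. lacZ is given above; lacY, the lactose permease gene, had a ratio of 3.20 ± 1.33 (SD, n = 3) and lacA, the acetyltransferase gene, 2.73 ± 1.24, with adjusted p-values of 0.0107 and 0.0149. As a list they had a camera adjusted p = 0.000162, and adjusted p = 0.398 with an estimated correlation. The textbook genotype of MC4100 lacks the chromosomal stretch from argF to lac. Of 18 tested genes of that stretch fixed beforehand, 0 passed, with a median of 0.17 and prpE at 0.93 ± 0.48 and cynX at 0.89 ± 1.08 as the largest (camera adjusted p = 0.170). The medians of this list in the 3 culture pairs were 0.42, 0.76 and -0.49. Without culture pair 3 the median was 0.75 and camera called the list (adjusted p = 5.36e-05), and without culture pair 2 the median turned to -0.26. On arrays 1, 4 and 5, of 1 dye orientation, the medians were 0.42, 0.92 and 0.26. On arrays 2 and 3, of the other orientation, they were -0.33 and -0.53, and with a dye term in the fit the median was -0.03. In all, camera called 16 of the 32 lists, 12 up and 4 down. The called lists are not all separate, since the hexitol list and most of the maltose list lie within the carbohydrate list. With an estimated correlation camera called 0 lists, and fry, which does not set a list against other genes, called 4. These were general stress and amino acid synthesis (fry adjusted p = 0.00932 for both), acid resistance (0.00971) and carbohydrate use (0.0195). The fry adjusted p was 0.0571 for curli and biofilm, 0.114 for iron uptake and for sulfate and cysteine, and 0.125 for the lac genes.

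The other genes with the largest rises were yddB and yddA, a predicted porin gene and a predicted transporter gene next to each other, at 3.19 ± 1.92 (SD, n = 3) and 2.55 ± 1.29. lrhA, a regulator gene, rose at 2.12 ± 0.31, grcA, which encodes a glycyl radical cofactor protein, at 2.00 ± 1.24 and at 1.29 without culture pair 3, and the prophage lysis genes rzpR and rzpD at 2.14 ± 0.99 and 1.95 ± 0.71. The rzp genes resemble each other, and their values are uncertain as separate measurements.

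Across genes, the dye effect estimated from culture pair 2 correlated with that from culture pair 3 at r = 0.30 (Spearman's rho 0.36) over 2540 genes, which are not independent replicates. Its SD over genes was 0.36 on the log2 scale. In a limma fit with a dye term 0 of 3530 genes had a dye effect at an adjusted p under 0.05, and 767 had one at an unadjusted p under 0.05. The latter is a larger share than the 0.05 expected by chance, so the count of 0 does not show that dye effects are absent. A dye effect cancels in culture pairs 2 and 3 where both arrays measured a gene and does not cancel in culture pair 1.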

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

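The tests of explanations in this part were chosen after the results were seen, except that the dye correlation of culture pairs 2 and 3 was planned before. The rule for single values was fixed beforehand and flags about 1 in 20 groups by chance; it flagged 4 of the 116 groups of array values examined. The 5 arrays include a pair of technical pairs, so they are not 5 independent samples. glpA was at 1.64 on array 2 and between 0.53 and 0.84 on the other arrays. osmY was at -3.66 on array 2 and between -3.18 and -3.00 on the others. fimE was at 1.63 on array 5 and between -0.13 and 0.29 on the others. ompC was at -1.86 on array 1 and between -3.13 and -2.94 on the others.

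Outside the open reading frames, 61.2% of the values of the 68 features named with L and a number were present, with a median log2 ratio of 1.19, against 9.29% of the values of buffer spots, 37.8% of those of features with yeast-like names (median 0.10) and 81.7% of those of features named with G and a number (median 0.05). The shares differ between arrays, from 32.4% to 91.2% for the L features and from 5.2% to 82.2% for the yeast-like ones, which had more values than the L features on array 4 (82.2% against 60.3%). The sources used here do not say what these features hold.

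Turning the ratio within culture pairs gives 4 distinct patterns, too few for a share under 0.05. The real pattern called 313 genes, and 1 pattern, the real one, gave a count as large; the highest of the others was 0.

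Arrays of 1 dye orientation and different culture pairs correlated across genes at a mean r of 0.58, above the 0.46 of the 2 arrays of 1 culture pair, a gap of 0.12. The single correlations overlap, at 0.49 to 0.70 and 0.39 to 0.54, and with so few arrays the gap has no error estimate here. The next 2 comparisons were judged on single array correlations, by a rule set, and later revised, with the values in view. Crossed technical pairs stay open: the labelled pairs correlated better than the crossed ones by 0.135 in the mean, but array 2 correlated at 0.39 with array 4, its labelled partner, and at 0.41 with array 5, while array 3 correlated at 0.54 with array 5, its labelled partner, and at 0.24 with array 4. Over the 1488 genes with both spots on all arrays both labelled pairs, at 0.61 and 0.69, lay above both crossed pairs, at 0.49 and 0.58. This argues against crossing, but the distance of 0.030 is smaller than the ranges of 0.079 and 0.090 within them. Missing spots stay open too: over the same genes the gap was 0.0717, with single correlations of 0.64 to 0.83 and 0.61 to 0.69. A gene-specific dye effect may contribute: the dye estimates of culture pairs 2 and 3 correlated at 0.296. That value is built from the same correlations between arrays 2 to 5, so it partly restates the pattern and is no separate test. For array 1, compared through arrays that enter only 1 side, the mean correlation was 0.197 (0.25 and 0.14), which leaves open how much of it a dye effect carries, and a hybridisation batch that follows the orientation was not tested.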

How the results depend on the processing

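Most alternatives were chosen before the data were examined; exact 1s read as unchanged and both spots only were added after. Of 61 called named genes, none turned direction in 1310 values over 22 alternatives, and 252 of those values lost the call. The absence of turns was largely fixed by selection, since called genes had the same sign in all culture pairs. With 313 called (89 higher, 224 lower) and 281 at least 2-fold (75 and 206), the counts moved over 1.5 times as follows; the cause was not tested unless given. All 5 arrays with the culture pair as a random block called 472, 168 higher; with a dye term 142 were higher. The series matrix called 480, 170 higher, over 3820 genes tested. Genes on all 5 arrays gave 146 higher. Genes in at least 2 culture pairs gave 185, 36 higher and 149 lower, with 185 at least 2-fold, 36 of them higher. Without moderation limma called 0 genes, 0 higher and 0 lower, with 589 at an unadjusted p under 0.05. Exact 1s read as unchanged gave 135 (29 higher, 106 lower), 131 at least 2-fold (28 and 103). An adjusted p under 0.1 gave 488 and under 0.01 gave 105. Leaving out 1 culture pair or array gave 8 to 501 genes, 0 to 168 higher, 8 to 333 lower, and 8 to 382 at least 2-fold, 0 to 114 higher and 8 to 268 lower. The lowest came without culture pair 1, where 470 genes had an unadjusted p under 0.05, and the highest without culture pair 3.

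Of 32 lists, 16 were called, 9 with arrays 1, 4 and 5 alone, 0 with an estimated correlation (lowest adjusted p = 0.207) and 4 by fry. Iron uptake had adjusted p = 0.380 with an estimated correlation and 0.114 by fry, amino acid uptake 0.349 and 0.120, carbohydrate use 0.301 and 0.0195. With arrays 1, 4 and 5 alone the medians of amino acid uptake and carbohydrate use were 0.15 and 0.12, not called; over all other settings these 3 lists were called by camera.

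Some values turned sign, and the cause was not tested. They include the called hexitol list, at a median of 0.28 in the results, and nuoK and nuoA, at 0.50 and 0.33 and not called. Leaving out 1 culture pair or array gave ranges of -0.0079 to 0.4303 for hexitol use, -0.4033 to 0.0611 for colanic acid, -0.0708 to 0.2595 for type 1 fimbriae, -0.4337 to 0.0432 for flagella, -0.2837 to 0.0324 for glycolysis, -0.1083 to 0.0403 for anaerobic respiration, -0.0231 to 0.0628 for membrane lipids, -0.2636 to 0.7527 for the argF to lac stretch and -0.0024 to 0.6682 for nuoA. Arrays 1, 4 and 5 alone gave -0.0901 for ribosomal proteins, -0.0329 for the respiratory chain, 0.0641 for anaerobic respiration, 0.0140 for membrane lipids, -0.0483 for nuoK and -0.1571 for nuoA. Arrays 1, 2 and 3 alone gave 0.1312 for glycolysis, 0.0589 for anaerobic respiration, 0.0567 for membrane lipids and -0.2238 for the argF to lac stretch. Membrane lipids were at 0.0065 with the random block, 0.0251 with the dye term, 0.0410 centred, 0.0548 scaled and 0.0199 after quantile normalization. The argF to lac stretch was at -0.0304 with the dye term, anaerobic respiration at 0.0185 over genes on all 5 arrays, and envelope stress at 0.0167 over genes in at least 2 pairs. The dye correlation stayed at 0.25 to 0.36. Signal over background is not analysed here. Leaving out culture pair 1, 2 or 3 let 3898, 3787 and 3553 genes be tested.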

Other observations

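Genes outside the fixed lists made up 194 of the 313 called, 42 higher and 152 lower at 37°C; those named here were chosen after their values were seen. Lower at 37°C were the glutaminase gene glsA at -3.79 ± 0.66 (SD, n = 3) and its neighbour ybaT at -3.35 ± 0.15, the putrescine breakdown genes patA and patD at -2.56 ± 0.40 and -2.60 ± 0.30, the ribosome-associated protein gene sra at -2.75 ± 0.63, the cytoplasmic amylase gene amyA at -2.58 ± 0.13 and the aldehyde dehydrogenase gene aldB at -2.41 ± 0.37. Of the second nitrate reductase, narZ, narV and narW fell at -1.28 ± 0.25, -1.73 ± 0.21 and -2.25 ± 0.28. Within culture pair 3 these genes were at -2.24, -2.77 and -4.09 on array 3, and at 0.09, -0.21 and -0.41 on array 5. The small protein genes yqjC, yqjD and yqjK fell at -1.64 ± 0.26, -2.01 ± 0.47 and -1.76 ± 0.18.

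Higher at 37°C were the cystine transport genes tcyN and tcyL at 1.35 ± 0.07 (SD, n = 3) and 1.18 ± 0.45, the thiosulfate uptake genes tsuA and tsuB at 1.17 ± 0.28 and 1.57 ± 0.74, the aldehyde reductase gene yqhD at 1.77 ± 0.20, the ribonucleoside hydrolase gene rihC at 1.83 ± 0.47 and the acetyl-CoA synthetase gene acs at 1.27 ± 0.13. Of 11 tested features for copies of the IS5 transposase, 9 were called, at 0.90 to 1.62 over all 11; the copies are near-identical, so they stand for 1 signal. Across 3356 genes in chromosome order, neighbouring genes' ratios correlated at r = 0.44, above the highest of 1000 shuffled orders, 0.07. Of 295 called genes, 144 had a called neighbour of the same direction, a count for which no shuffled value is given.

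The tests of the 2 patterns below were chosen after the results were seen, although the fit with a dye term and the gene lists were planned before. lacZ, lacY and lacA were higher at 37°C although the strain's textbook genotype lacks them. Of the 65 features from argF to lacI other than these, 32.3% could be tested, against 83.3% of all other features. The highest ratio among them was 0.927, below lacA at 2.73, which argues against a shift common to features the strain lacks as the whole of the lac rise. A smaller shift of those features is not excluded, with list medians of 0.42 and 0.76 in culture pairs 1 and 2. The sign of the list median followed dye orientation, however: above 0 on arrays 1, 4 and 5 and below 0 on arrays 2 and 3. With a dye term in the fit the median was -0.0304. Against a dye effect, the lowest of the 3 temperature ratios in the fit with a dye term was 2.59, all called; a bound of 1 first set for every single array was missed by lacA on array 5, at 0.98. A candidate explanation is a lac reporter carried by the strain under the papBA promoter, which the design text names as a control; lacI at 0.744 ± 0.94 (SD, n = 3; adjusted p = 0.282) does not decide it, and no pap feature was on the array.

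RpoS-dependent genes were lower at 37°C by a median of -1.82. Against a dye effect, the median over the dye-swapped culture pairs alone was -1.71. Whether the 23°C cultures were further out of exponential phase cannot be told apart from temperature: ribosomal protein genes had a median of 0.109 (quartiles -0.03 and 0.25), fis was at -0.54 ± 0.43 (SD, n = 3; adjusted p = 0.240), rmf fell at -1.35 ± 0.76 and sra as above, and how far each would move is not known here. An effect of temperature itself, which the design names, stays open and untested beyond the comparison. The question of growth phase is equally open for the acid resistance and curli lists, for which it was not tested.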
